A study of Homo sapiens with 504 samples.

How the data were processed

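Human aortic endothelial cells of separate donors were profiled by RNA-seq, ATAC-seq and ChIP-seq in control medium or with 10 ng/mL IL-1B. The groups, donors and treatments were read from the sample labels. For IL-1B ATAC libraries the title and the treatment field gave IL-1B while the source field gave untreated, and the title was followed. For 1 donor the titles of the untreated RNA libraries and the donor field disagreed, and the title was followed, with the donor left out as an alternative. The treatment time is not given in the sources used here. Input libraries had no file that was analysed.

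The RNA table holds RPKM values that the authors made from reads aligned to hg19, per the submitters' processing notes, which name STAR, Bowtie2 and HOMER without versions. The authors had pooled the libraries of each donor and treatment into 1 column, with 2 libraries behind most columns and 1 to 4 behind the others. The values were whole multiples of a step in each column, which gave the read depth. The values also behaved as if at most 1 read was counted per position, which is an inference, and the ceiling this sets averaged 84.2 RPKM in untreated and 88.5 RPKM in IL-1B columns. Depth is given with the results.

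The peak files are HOMER peak lists made by the authors for each donor, per the file headers. ATAC peaks were called with a size of 75 bp, at least 8-fold over the local background and no input. H3K27ac peaks were called with a size of 500 bp against pooled input at 4-fold, and ERG and p65 peaks in the factor style at a false discovery rate of 0.001 and 4-fold over pooled input. The score of each peak is the authors' HOMER value in the deposited files, and the signal is the deposited tag count of the peak normalised to 1e+07 tags, per the file headers. Cells for ChIP-seq were fixed with formaldehyde, per the labels, and the lists hold chromosomes 1 to 22 and X. Median shares of tags in peaks were 11.2% in untreated and 9.96% in IL-1B ATAC libraries, 49.1% and 48.7% for H3K27ac, 3.68% for ERG and 13.7% for p65.

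The table held 26457 rows, of which 113 for Y-linked genes, XIST and TSIX were left out. The 14308 genes with a mean of at least 0.5 RPKM were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3. The test was on the IL-1B minus untreated difference within each donor, two-sided, with a variance trend over mean log expression and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and at least 2-fold at a mean log2 difference of 1 or more in size. The 26 gene lists were written before the data were examined and tested with camera of limma at a preset correlation of 0.01 and with an estimated correlation, and with fry, whose directional test asks about a change one way on balance and whose mixed test about changes in either direction. Named genes were the 15 highest and 10 lowest 2-fold genes that moved the same way in at least 90% of donors and reached 2 RPKM, up to 3 genes of each list and 10 genes fixed in advance.

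ATAC and H3K27ac regions were stretches of at least 50 bp covered by peaks of at least 5 libraries. Presence in a library was overlap by at least 1 bp, and gains and losses were tested with an exact two-sided McNemar test over donors, adjusted by Benjamini-Hochberg. Peak numbers were compared by two-sided sign-flip permutation over 100000 resamples. Common p65 and ERG sites were stretches found in at least 50% of donors. Their overlap with regions was compared with uncalled regions of the same occupancy, and sites and regions near genes were counted within 50 kb of the transcription start, by two-sided Fisher's exact tests. Start positions came from the RNA table, in hg19, with the start of 1 transcript per row, so other starts of a gene were not examined. Where every called gene had a feature, the odds ratio was infinite, and the listed alternative value has 0.5 added to each count. Genes and regions are not independent replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

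Donor pairing was checked by correlating donor profiles between treatments, and 52 of 53 columns correlated best with the column of the same donor. The RNA test was tested on simulated data with 100 genes changed by 0.5 and 100 by 1.5 on the log2 scale, all recovered, with 9 unchanged genes called of 14308. The region test on simulated data of 20000 regions and 37 pairs recovered 95.5% of 200 changed regions, with 5 unchanged regions called. The changed regions were set at 10% occupancy in 1 state and 70% in the other. Regions were simulated as independent, without differences between whole libraries. Recovery of smaller changes, and errors where libraries differ in quality, were thus not measured.

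The comparisons, tests, lists, naming rules and first alternatives were fixed before the data were examined. The alternatives fixed then were a pseudocount of 0.1, no or a stricter expression filter, quantile normalization, equal column medians, no donor block (for peaks and regions with all libraries, by unpaired tests), a sign test, an estimated list correlation, other distances, backgrounds, site thresholds and peak subsets. Several choices came after the data were seen. The variance trend was first fitted over the mean difference, and was changed to mean log expression after GJA5, lower in 53 of 53 donors, lost its call without the expression filter. For the same reason camera was run on the donor-blocked design over all columns, in place of the donor differences that had been planned. Both forms called 261 genes higher and 61 lower at 2-fold. The ceiling correction, pairs matched on depth or tags in peaks with 20 random draws, backgrounds of the same width or of the same occupancy where the factor was mapped, removal of outlying donors, ERG sites near genes and the correlation of donor levels were also added then. The outcome of the p65 hypothesis was changed from fitting to undecided after the correlation without outlying donors was seen, and the scaling test was made undecided since centring fixes its outcome. Libraries had been planned to be averaged on the log2 scale, but the table had them pooled, so tests of donor variation, of donor by treatment and of single replicates were not run, and the correlation over donors took their place.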

Results

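Human aortic endothelial cells, which line the inside of the aorta, were grown from separate donors and studied at passages 6 to 10. Cells of the same donors were kept in medium with 1% fetal bovine serum, either untreated or with 10 ng/mL IL-1B, a cytokine released in inflammation. RNA-seq covered 53 donors in both states, with 104 untreated and 107 IL-1B libraries. Open chromatin was mapped by ATAC-seq in 44 untreated and 43 IL-1B libraries, 1 per donor. ChIP-seq for H3K27ac, a histone mark of active promoters and enhancers, covered 42 donors in each state, with 48 untreated and 44 IL-1B libraries. ChIP-seq for ERG, a transcription factor of endothelial cells, was done in untreated cells of 22 donors (25 libraries). ChIP-seq for p65, the NF-kB subunit encoded by RELA, was done in IL-1B treated cells of 36 donors (37 libraries).

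The RNA values were RPKM, with the libraries of each donor and treatment already pooled into 1 column. The steps between low values put the depth behind a column at 12.6 ± 3.59 M reads in untreated cells and 11.65 ± 2.11 M reads with IL-1B (mean ± SD, n = 53 donors). The difference of -0.952 M reads per donor passed a two-sided sign-flip permutation test (p = 0.00859). The peak lists rested on a median of 11.5 M tags in untreated and 11 M in IL-1B ATAC libraries. The median was 13.6 M in untreated and 12.3 M in IL-1B H3K27ac data, 8.69 M for ERG and 9.46 M for p65. The p65 data ranged from 3.32 to 24.8 M tags.

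The first comparison asked which transcripts IL-1B changed in these cells. RNAs for chemokines, colony-stimulating factors, adhesion molecules and NF-kB feedback regulators rose, and the largest fall was in a gap junction gene of arterial endothelium. Of 14308 genes tested, 261 were at least 2-fold higher and 61 at least 2-fold lower with IL-1B (limma on the differences within donors, Benjamini-Hochberg adjusted p under 0.05). CX3CL1 (NM_002996, hg19 chromosome 16, 57406373 to 57418960), a membrane-bound chemokine, averaged 4.49 ± 9.59 RPKM in untreated and 54.6 ± 7.38 RPKM in IL-1B cells (mean ± SD, n = 53 donors). Its mean donor difference was 4.30 ± 0.17 (SE) in log2(RPKM + 1), with adjusted p = 1.63e-30, and it was higher in 53 of 53 donors. CCL20 (NM_001130046, chromosome 2, 228678558 to 228682280), a chemokine that draws lymphocytes and dendritic cells, rose from 2.42 ± 5.07 to 41.05 ± 8.28 RPKM (log2 difference 4.29 ± 0.16 SE). CSF2 (NM_000758, chromosome 5, 131409485 to 131411863), the growth factor GM-CSF, rose from 3.16 ± 6.43 to 40.5 ± 4.98 RPKM (4.12 ± 0.16 SE). IL1B itself (NM_000576, chromosome 2, 113587337 to 113594356) rose from 4.11 ± 8.06 to 44.0 ± 11.3 RPKM (3.88 ± 0.15 SE), so the treated cells held more transcript of the cytokine they were given.

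The next highest genes by the same log2 difference were C2CD4A (4.03), the hyaluronan-binding protein gene TNFAIP6 (3.95), the ubiquitin-like modifier UBD (3.95) and the NF-kB regulator TNIP3 (3.77). TRAF1, an adaptor of TNF receptors, rose by 3.71, and the interferon-inducible chemokine CXCL10 by 3.64. MSC (3.63), the cytokine LIF (3.61), the apoptosis inhibitor BIRC3 (3.60), C2CD4B (3.47) and CSF3 (3.35), the growth factor G-CSF, completed the 15 highest. All of these were higher in 53 of 53 donors, except LIF in 52. GJA5 (NM_181703, chromosome 1, 147228332 to 147232714), which encodes a gap junction protein of arterial endothelium, had the largest fall, from 14.1 ± 8.28 to 2.16 ± 2.16 RPKM. Its log2 difference was -2.25 ± 0.076 (SE, adjusted p = 8.49e-34), and it was lower in 53 of 53 donors. TMEM37 (-1.91), NRROS (-1.89), FAM78A (-1.63), FAM212A (-1.56) and FAM110D (-1.5) followed. The planar cell polarity gene PRICKLE1 (-1.47), the pyruvate dehydrogenase kinase gene PDK4 (-1.46), FAXDC2 (-1.45) and PPP1R3C (-1.44), which directs a phosphatase to glycogen, completed the 10 lowest. PDK4 was lower in 48 of 53 donors and the other 9 genes in at least 51.

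Without the fold limit, 3950 genes were higher and 6597 lower at adjusted p under 0.05, so 37.5% of the called genes were higher. With the median of every column made equal, 5462 were higher and 5947 lower, or 47.9% higher. The median log2 difference over all tested genes was -0.045. Among genes with a mean of at least 5 RPKM it was -0.013, with 3343 higher and 4204 lower (44.3% higher). With a pseudocount of 0.1 in place of 1, 378 genes were at least 2-fold higher and 329 at least 2-fold lower, and CXCL10 (5.74), TNFAIP6 (5.62), MSC (5.53), CCL20 (5.46) and CSF2 (5.134) stood above CX3CL1 (5.126). PPP1R3C was at -2.38 and ICAM4 at 2.59 with that pseudocount. The RPKM values of abundant genes stopped near a ceiling in each column, as if at most 1 read was counted per position, and such a ceiling understates the folds of genes that rose to high levels.

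Genes fixed in advance as markers of endothelial activation were all higher. SELE (NM_000450, chromosome 1, 169691781 to 169703220), which encodes E-selectin, rose from 14.1 ± 19.2 to 72.0 ± 10.1 RPKM (log2 difference 2.85 ± 0.15 SE, adjusted p = 2.47e-25, higher in 52 of 53 donors). VCAM1 (NM_001078, chromosome 1, 101185196 to 101204601), a ligand for leukocyte integrins, rose from 14.2 ± 15.9 to 70.6 ± 10.7 RPKM (2.66 ± 0.13 SE). ICAM1 rose by 1.65 ± 0.084, CCL2 by 1.45 ± 0.078, CXCL8 by 1.42 ± 0.082 and NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, by 1.38 ± 0.051. In IL-1B cells the mean level of SELE stood at 81.9% of the ceiling, that of VCAM1 at 80.2% and that of ICAM1 at 85.1%. With values corrected for the ceiling, the differences of these genes were 3.75, 3.52 and 2.52. RELA rose by 0.22 ± 0.026 (0.13 after quantile normalization) and the IL-1 receptor gene IL1R1 by 0.28 ± 0.038. ERG fell by 0.15 ± 0.024 and KLF2, a flow-induced transcription factor gene, fell by 0.41 ± 0.078, lower in 39 of 53 donors.

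**Figure D1:**
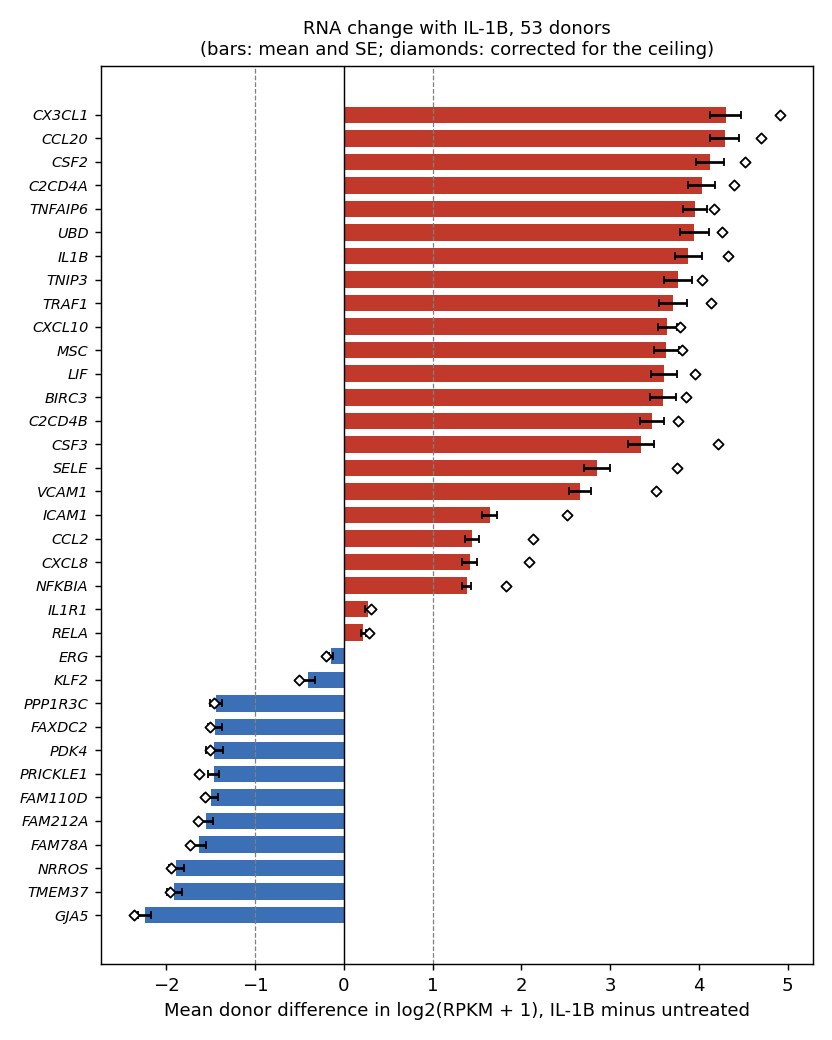
Change in RNA with IL-1B for the 15 highest genes, the 10 lowest genes and the 10 genes fixed in advance. Bars give the mean donor difference in log2(RPKM + 1), IL-1B minus untreated, and error bars the SE over 53 donors; diamonds give the difference after correction for the ceiling, and dashed lines mark 2-fold. CX3CL1 lies highest at 4.30 and GJA5 lowest at -2.25, and the diamonds of SELE, VCAM1 and ICAM1 lie well beyond their bars.

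Lists of inflammatory genes fixed in advance rose as groups. Of 18 chemokines tested, 14 rose, each at least 2-fold, and 2 fell, with a median log2 difference of 1.99 (camera adjusted p = 1.09e-10, and adjusted p = 0.078 with an estimated correlation). Of 22 cytokines and growth factors, 19 rose and 1 fell (median 1.40, adjusted p = 3.56e-14, and adjusted p = 0.0505 with an estimated correlation). Of 28 NF-kB factors and feedback inhibitors, 27 rose, 17 of them at least 2-fold, and 1 fell (median 1.27, adjusted p = 1.06e-21, and adjusted p = 0.078 with an estimated correlation). Of 13 leukocyte adhesion molecules, 10 rose and 1 fell (median 0.31, adjusted p = 1.03e-05, and adjusted p = 0.12 with an estimated correlation). SELE, ICAM4 (1.68), VCAM1 and ICAM1 were the 4 adhesion genes that rose at least 2-fold. The untreated levels of many of these genes varied widely between donors, with SDs above the means for CX3CL1, CCL20, CSF2 and SELE. The RNA response of a donor was its mean log2 difference over the 261 genes called at least 2-fold higher. In 7 of 53 donors it was outlying low, and without these donors 295 genes were at least 2-fold higher and 82 at least 2-fold lower. Leaving out the lowest responses raises the means of the same genes, so the larger number of higher genes was largely built in.

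Interferon and immediate early genes moved the same way. Of 33 interferon-stimulated genes, 28 rose and 1 fell (median 0.55, camera adjusted p = 1.4e-13, and adjusted p = 0.0831 with an estimated correlation). RSAD2, an antiviral enzyme gene, rose by 1.58, the exonuclease gene ISG20 by 1.43 and OASL by 1.40, while with a pseudocount of 0.1 RSAD2 rose by 2.73 and OASL by 2.28. Of 16 genes for interferon regulatory factors and antigen presentation, 15 rose and 0 fell (median 0.29, adjusted p = 4.41e-08, and adjusted p = 0.12 with an estimated correlation). IRF1 rose by 1.11, HLA-F by 1.04 and IRF2 by 0.74. Of 20 AP-1 and immediate early genes, 17 rose and 2 fell (median 0.38, adjusted p = 1.16e-08, and adjusted p = 0.078 with an estimated correlation), led by ATF3 (2.81), BATF3 (1.67) and JUNB (1.13).

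Genes of clotting, matrix turnover and small mediators also rose more often than they fell. F3, which encodes tissue factor, the starter of the extrinsic clotting cascade, rose from 3.57 ± 4.94 to 30.5 ± 5.37 RPKM (3.18 ± 0.12 SE), while THBD, the anticoagulant receptor thrombomodulin, fell by 0.79 ± 0.040. Of 17 coagulation and fibrinolysis genes, 10 rose and 4 fell (median 0.21, camera adjusted p = 0.00416, and adjusted p = 0.332 with an estimated correlation). Of 16 matrix proteases and inhibitors, 9 rose and 3 fell (median 0.33, adjusted p = 0.000583, and adjusted p = 0.236 with an estimated correlation), with MMP10 at 1.66, CTSS at 1.498 and MMP12 at 1.33, which was 3.47 with a pseudocount of 0.1. Of 11 prostanoid, superoxide and nitric oxide enzymes, 6 rose and 4 fell (median 0.60, adjusted p = 0.01, and adjusted p = 0.244 with an estimated correlation). GCH1, which makes the cofactor of nitric oxide synthases, rose by 2.17, the cyclooxygenase gene PTGS2 by 2.01 and the mitochondrial superoxide dismutase gene SOD2 by 1.31. With values corrected for the ceiling, these differences were 2.419, 2.536 and 1.995. Of 18 unfolded protein response genes, 15 rose and 0 fell (median 0.20, adjusted p = 1.03e-05, and adjusted p = 0.244 with an estimated correlation), with DNAJB9 at 1.35 and HERPUD1 at 0.73. Of 16 apoptosis regulators, 12 rose and 3 fell (median 0.24, adjusted p = 0.000161, and adjusted p = 0.241 with an estimated correlation). The anti-apoptotic BCL2A1 rose by 1.67 and the pro-apoptotic PMAIP1 by 1.12, while CASP8 fell by 0.63. Of 16 genes of mesenchymal transition, 8 rose and 2 fell (median 0.083, adjusted p = 0.0178, and adjusted p = 0.421 with an estimated correlation), with TWIST1 at 0.66 and SNAI1 at 0.63.

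Genes that define endothelial cells went both ways. Of 28 endothelial identity genes, 10 rose and 13 fell, against 8 and 20 after quantile normalization (median -0.108), and camera did not set the list apart from other genes and leaned up where the median was -0.04 and the mean -0.025 (adjusted p = 0.525). The transcription factor gene ETS1 rose by 0.95, while SOX18 fell by 0.95 and LYL1 fell by 0.66. Of 12 flow-responsive vasoprotective genes, 3 rose, among them KLF4 (1.04), and 8 fell (median -0.15, adjusted p = 0.525). Of 13 Notch signalling genes, 5 rose and 6 fell (median -0.044 but mean 0.075 and camera leaning up, adjusted p = 0.601), with the target HEY1 at 1.73, the ligand JAG1 at 0.80 and the arterial ligand DLL4 at -1.02. Of 23 TGF-beta and BMP signalling genes, 8 rose and 9 fell (median -0.011 but mean 0.12 and camera leaning up, adjusted p = 0.13), with TGFB3 at 1.84, INHBA at 1.34 and TGFB2 at 1.25. Of 18 angiogenic factors and receptors, 7 rose and 8 fell (median -0.009 but mean 0.066 and camera leaning up, adjusted p = 0.284), with HBEGF at 0.75, ESM1 at 0.72 and VEGFC at 0.72. The medians of the TGF-beta and angiogenic lists turned to 0.025 and 0.027 with equal column medians. With that setting 9 TGF-beta genes rose and 6 fell, and 8 angiogenic genes rose and 8 fell. The mixed test of fry, which asks whether members change in either direction, gave adjusted p = 4.61e-23 for endothelial identity and 2.93e-20 for TGF-beta and BMP signalling. The directional test of fry, which asks whether members change one way on balance, gave adjusted p = 3.11e-05 for a fall of the flow-responsive genes and 0.000632 and 0.00167 for rises of the TGF-beta and angiogenic lists, and neither fry test compares a list with other genes.

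Camera called no list lower on the main values. Of 28 cell cycle genes, 0 rose and 18 fell (median -0.088, camera adjusted p = 0.0888), with E2F2 at -0.72, CDCA7 at -0.66 and CCNE1 at -0.35. With equal column medians 4 cell cycle genes rose and 16 fell. With values corrected for the ceiling, camera at the preset correlation gave adjusted p = 0.0221 for a fall. On the main values with an estimated correlation, camera gave adjusted p = 0.801. The directional test of fry gave adjusted p = 1.33e-05 for a fall of the cell cycle list, 1.01e-05 for leukocyte markers and 0.0119 for lymphatic markers. Of 19 cholesterol synthesis and uptake genes, 8 rose and 8 fell (median 0.017 and camera leaning up but mean -0.011, adjusted p = 0.51), with INSIG1 at 0.58, SC5D at -0.59 and MVK at -0.51. The median of that list was -0.013 after quantile normalization. Of 20 glycolysis genes, 10 rose and 4 fell (median 0.057, adjusted p = 0.117), against 5 that rose and 10 that fell after quantile normalization. PFKFB3, which makes an activator of glycolysis, rose by 0.98 and the hexokinase gene HK2 by 0.46. Of 18 housekeeping genes, 9 rose and 1 fell (median 0.057, adjusted p = 0.192), against 4 and 7 after quantile normalization, with RAB7A at 0.13 and VCP at 0.11, which were 0.034 and 0.022 after it.

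Markers of other cell types did not move as groups in camera. Among smooth muscle markers, 5 were abundant enough to test, of which 2 rose and 1 fell (median -0.043 but mean 0.025 and camera leaning up, adjusted p = 0.525, and median 0.014 after quantile normalization). Their differences were 0.20 for CALD1, 0.16 for SMTN and -0.14 for MYLK, and after quantile normalization 0.12, 0.082 and 0.014. Of 11 fibroblast markers, 4 rose and 2 fell (median 0.006, adjusted p = 0.284), with DCN at 0.35 (0.57 with a pseudocount of 0.1) and PDGFRA at 0.43, from 0.504 to 0.99 RPKM, which was 1.11 with a pseudocount of 0.1. For the fibroblast list fry gave adjusted p = 0.00921 for a rise on balance and 5.83e-06 in the mixed test. Of 5 leukocyte markers, 0 rose and 3 fell (median -0.09, adjusted p = 0.525), with CORO1A at -0.28, CD14 at -0.14 and ITGAX at -0.09. After quantile normalization CORO1A was -0.14, CD14 was -0.008 and no longer passed (limma adjusted p = 0.829), and ITGAX turned to 0.032. Of 4 lymphatic endothelial markers, 1 rose and 2 fell (median -0.035, against 0.048 after quantile normalization and 0.001 with equal column medians, adjusted p = 0.99), with PROX1 at -0.51, RELN at 0.13 (0.32 with a pseudocount of 0.1) and FLT4 at -0.097, which no longer passed after quantile normalization (-0.03, limma adjusted p = 0.299). With a pseudocount of 0.1, PROX1 was -0.741, FLT4 -0.203, CORO1A -0.326, CD14 -0.221 and ITGAX -0.167. Adjusted over the list alone, the numbers that rose and fell were the same as over all genes in every list but 4. The exceptions were 16 that rose among interferon regulatory and antigen presentation genes, 8 among angiogenic factors, 9 among glycolysis genes and 8 among housekeeping genes. The camera calls of the 13 lists above their threshold did not hold with an estimated correlation, where 0 of 26 lists passed at an adjusted p and 7 passed at an unadjusted p under 0.05.

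The study compared donors as well as treatments, so the level of each gene was correlated between the untreated and IL-1B cells of the same donors. In 12965 of 14308 genes (90.6%) donors with a higher untreated level also had a higher IL-1B level (one-sided test against shuffled donors, adjusted p under 0.05). The median Pearson r was 0.487 and the shuffled median 0.0023. With the first 3 principal components, the main axes of variation over donors, removed in each state, 11765 genes (82.2%) passed, with a median r of 0.421. Among genes above 5 RPKM on the autosomes, the highest correlations were in the fibrillin gene FBN2 (r = 0.993, rho = 0.989), the potassium channel subunit gene KCNAB1 (r = 0.992, rho = 0.975) and the glutathione transferase gene GSTT1 (r = 0.992, rho = 0.884). CECR1 and PLCB2 (both r = 0.988), the retinoic acid enzyme gene ALDH1A2 (0.987), PAX8-AS1 (0.986), IGFBP2 (0.985), the collagen gene COL3A1 (0.983) and the peptide-trimming enzyme gene ERAP2 (0.981) followed. Each had a permutation p of 1e-05 for r and for rho, the smallest that 100000 resamples allow, and r stayed at 0.978 or more without the 2 donors farthest from the median. For SELE and VCAM1 the donor levels were not shown to be correlated between the states. SELE had r = 0.0382 (adjusted p = 0.404) and VCAM1 had r = 0.0897 (adjusted p = 0.27), with an SD of the log2 level over donors of 1.12 in untreated and 0.206 in IL-1B cells for SELE. In IL-1B cells both genes stood near the ceiling, where values are compressed, so a correlation could be missed, and with values corrected for the ceiling r was 0.0418 and 0.11. IL1R1 had r = 0.856. By the same test ICAM1, at 85.1% of the ceiling in IL-1B cells, passed (r = 0.267, adjusted p = 0.0311). KLF2, at 26.2% of it, did not (r = -0.181, adjusted p = 0.909), nor did CCL2 (r = 0.207, adjusted p = 0.0736). Nearness to the ceiling alone thus did not set which genes passed. Donor, culture and processing day cannot be told apart in this comparison, which replaced planned tests on separate libraries.

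The second comparison asked where IL-1B changed open chromatin and H3K27ac. IL-1B opened more regions than it closed, while more regions lost H3K27ac than gained it. Among 153554 ATAC regions compared over 37 donors with both states, 6218 were gained and 2497 lost (exact McNemar test over donors, Benjamini-Hochberg adjusted p under 0.05). Among 66033 H3K27ac regions compared over 38 donors, 5213 were gained and 9266 lost. The number of ATAC peaks per library averaged 79966 ± 31230 in untreated and 79399 ± 41790 in IL-1B cells (SD, n = 37 donors), a mean difference of -567.1 that did not pass a two-sided sign-flip permutation test (p = 0.957). H3K27ac peaks fell from 42196 ± 3327 to 40495 ± 4234 (n = 38 donors), a mean difference of -1701 (p = 0.00466, two-sided sign-flip permutation test). For H3K27ac peaks per library among the higher-scoring 50%, the mean fall was larger but did not pass the same test (p = 0.0933). The IL-1B H3K27ac data were also shallower, and the mean tag number fell by 2368000, from 15425000 to 13057000 (p = 0.0636). In the 20 donor pairs with a depth ratio under 1.5, 2472 H3K27ac regions were gained and 3184 lost. Gains were thus 43.7% of called regions in these pairs, against 36.0% in all 38 pairs.

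Where changed regions of both marks overlapped, they mostly changed the same way. Of the gained ATAC regions, 27.6% overlapped a gained H3K27ac region and 0.74% a lost one. Of the lost ATAC regions, 0.2% overlapped a gained H3K27ac region and 26.5% a lost one. The ATAC regions with the most donors gaining them lay on chromosome 1 at 60171541 to 60171840, within the transcript of FGGY, and on chromosome 17 at 9292336 to 9292765, within the transcript of STX8. Each was gained in 33 of 37 donors and lost in 0, with an adjusted p of 1.79e-05, and held a common p65 site. The region lost in the most donors was on chromosome 11 at 12040941 to 12041271, with the start of DKK3 at 10919 bp, and it was lost in 31 donors and gained in 1. Among gained H3K27ac regions, more than 5 tied for the highest rank, and 5 of them were named by their order along the genome. These 5 were called in 38 of 38 donors with IL-1B and in 0 without, and all held a common p65 site. They included chromosome 1, 56912073 to 56919470, with the start of PLPP3 at 129486 bp, and chromosome 2, 192029932 to 192033411, with the start of STAT4 at 15349 bp. The H3K27ac region on chromosome 15 at 68996386 to 68998140, within the transcript of CORO2B, was lost in 37 of 38 donors and gained in 0 (adjusted p = 3.77e-08), and held both a p65 and an ERG site.

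Among the 15 highest genes and the 6 genes fixed in advance that rose at least 2-fold, 21 in all, 15 had a gained ATAC region within 10 kb of the start, 14 a gained H3K27ac region, 9 both and 1, TRAF1, neither, and NFKBIA also had a lost ATAC region. Of the 29 strongest gained regions at these genes, 1 per gene and mark, 18 held a common p65 site. Those without were at CX3CL1, CCL20, CSF2, C2CD4A, UBD, CCL2, NFKBIA, CXCL8 (both marks), CXCL10 (H3K27ac) and MSC (ATAC). At the SELE promoter, an ATAC region (chromosome 1, 169703098 to 169703393) was called in 31 IL-1B and 14 untreated libraries of 37 donors (adjusted p = 0.00454). An H3K27ac region there (169700285 to 169704621) was called in 33 IL-1B and 0 untreated libraries of 38 donors (adjusted p = 9.32e-08). At TNFAIP6, an ATAC region (chromosome 2, 152220311 to 152220517) was called in 32 against 4 libraries and an H3K27ac region (152218501 to 152221706) in 36 against 0. At CSF3, an ATAC region (chromosome 17, 38171390 to 38171829) was called in 27 against 2 libraries. Upstream of ICAM1, an ATAC region (chromosome 19, 10376115 to 10376331) was called in 29 against 2, and an H3K27ac region spanning the start of VCAM1 (chromosome 1, 101184263 to 101191177) in 38 against 15. These 7 regions were among those with a common p65 site. Of the 10 lowest genes, 5 had a lost H3K27ac region, 2 a lost ATAC region and 3 neither, and FAXDC2 had a gained ATAC region as well. KLF2 and ERG, which fell less, each had a lost ATAC region. At genes that fell, H3K27ac regions were lost at TMEM37 (chromosome 2, 120188788 to 120190246, 1 IL-1B against 25 untreated libraries) and PPP1R3C (chromosome 10, 93392115 to 93393557, 7 against 30). No gained or lost region lay within 10 kb of the start of GJA5, while within 50 kb lay gained ATAC regions with p65 sites, against the fall of its RNA, and a lost H3K27ac region.

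The counts moved with the peaks compared, with 2560 ATAC regions gained and 1133 lost, and 3332 H3K27ac regions gained and 4370 lost, when the same number of top-scoring peaks was kept in every library. In the 21 donor pairs whose shares of tags in peaks were within 1.5-fold, 0 ATAC regions passed the McNemar test after adjustment and 13553 had an unadjusted p under 0.05, while 21 pairs drawn at random also gave a median of 0.

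The third comparison placed the transcription factors p65 and ERG on these regions. Regions that opened with IL-1B were mostly p65 sites, and held p65 more often than uncalled regions under every matching used. Differences in ERG mostly ended when regions were matched on how often they were found in untreated cells, where ERG was mapped. In IL-1B cells, 50348 common p65 sites were found in at least 18 of 36 donors, and in untreated cells 17163 common ERG sites in at least 11 of 22 donors. A common p65 site lay in 74.7% of gained ATAC regions (95% Wilson interval 73.6 to 75.7) against 27.1% of uncalled regions of the same occupancy (odds ratio 7.91, two-sided Fisher's exact test, p below 1e-300). For gained H3K27ac regions the shares were 71.9% and 40.6% (odds ratio 3.74, p = 5.08e-231). Common ERG sites lay in 22.9% of lost ATAC regions against 8.93% of matched regions (odds ratio 3.04, p = 1.2e-42), and in 3.01% of gained ATAC regions against 7.35% (odds ratio 0.391, p = 2.32e-28). They lay in 16.3% of lost H3K27ac regions against 8.3% (odds ratio 2.16, p = 7.72e-63), and in 3.01% of gained H3K27ac regions against 7.81% (odds ratio 0.367, p = 6.11e-28).

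ERG was mapped only in untreated cells, where lost regions are found more often than gained ones, and p65 only in IL-1B cells, where the reverse holds, so part of these differences follows from the design. Against uncalled regions found as often in the state where the factor was mapped, the odds ratios of p65 sites were 3.87 in gained ATAC regions (p = 3.66e-283) and 1.94 in gained H3K27ac regions (p = 1.38e-57). Those of ERG sites were 1.32 in lost ATAC regions (p = 7.74e-05), 1.0 in lost H3K27ac regions (p = 0.921), 0.919 in gained ATAC regions (p = 0.44) and 1.19 in gained H3K27ac regions (p = 0.171). Called ATAC regions were also wider, with medians of 207 bp for gained and 223 bp for lost against 152 bp for uncalled regions. Against regions of the same occupancy and width, the odds ratio was 5.53 for p65 sites in gained ATAC regions (p below 1e-300) and 2.27 for ERG sites in lost ATAC regions (p = 2.03e-26).

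**Figure D2:**
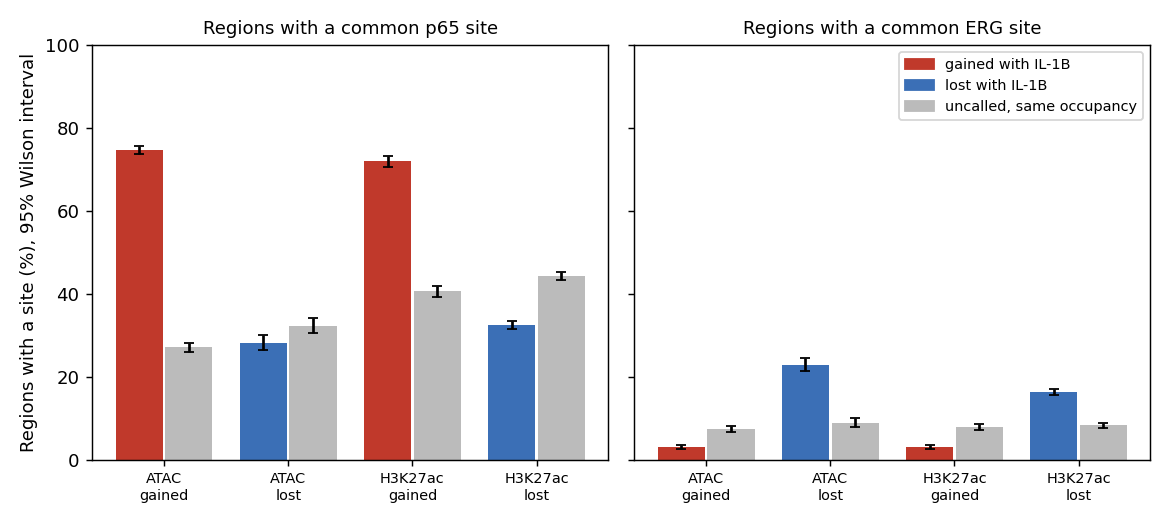
Share of regions that held a common p65 site (left) or a common ERG site (right), in percent with 95% Wilson intervals. Red bars are regions gained with IL-1B, blue bars regions lost, and grey bars uncalled regions of the same occupancy. Gained ATAC regions held p65 sites in 74.7% and ERG sites in 3.01%, and lost ATAC regions held ERG sites in 22.9%. The grey regions were matched on occupancy over both states.

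Lost regions held p65 less often than matched regions, at 28.2% against 32.3% of ATAC regions (odds ratio 0.824, p = 0.00186) and 32.5% against 44.2% of H3K27ac regions (odds ratio 0.607, p = 1.61e-60). Both turned against regions found as often in IL-1B cells, to odds ratios of 1.69 (p = 6.67e-15) and 1.34 (p = 1.72e-19). The p65 result for lost ATAC regions ended with all uncalled regions as background (odds ratio 1.01, p = 0.822), and the ERG result for lost H3K27ac regions turned with that background (odds ratio 0.623, p = 1.12e-60). Both factors shared many places, since 27.4% of common p65 sites overlapped a common ERG site and 80.3% of common ERG sites overlapped a common p65 site. ATAC regions with a p65 site held an ERG site in 30.4%, against 2.23% of those without (odds ratio 19.1, Fisher's exact test, p below 1e-300). This contrast was not matched on occupancy or width, so how often regions were found open may account for part of it. ERG was mapped in untreated and p65 in IL-1B cells alone, so neither factor could be compared between the states, and regions are not independent replicates.

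The fourth comparison joined regions and sites to genes by distance from the transcription start. Gained regions lay near genes that rose and lost regions near genes that fell. A gained ATAC region lay within 50 kb of 59.0% of the 261 genes that rose at least 2-fold. The share was 24.7% in the 13986 tested genes not called at 2-fold (odds ratio 4.39, two-sided Fisher's exact test, adjusted p = 2.05e-30). Many of these 13986 genes changed by less than 2-fold at adjusted p under 0.05, so they are not a set of unchanged genes. A gained H3K27ac region lay near 59.0% against 19.8% (odds ratio 5.83, adjusted p = 1.08e-41). Of the 61 genes that fell, 45.9% had a lost ATAC region against 20.1% (odds ratio 3.38, adjusted p = 1.5e-05), and 77.0% had a lost H3K27ac region against 39.8% (odds ratio 5.08, adjusted p = 2.13e-08). Genes that rose had a lost H3K27ac region less often, at 18.4% (odds ratio 0.341, adjusted p = 8.56e-13), and a lost ATAC region at 13.8% (odds ratio 0.637, adjusted p = 0.0181). The last of these did not pass against a smaller set of genes matched on mean expression (odds ratio 0.717, p = 0.0753), and passed within 10 kb (0.413, p = 0.00964) and 200 kb (0.707, p = 0.00699).

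**Figure D3:**
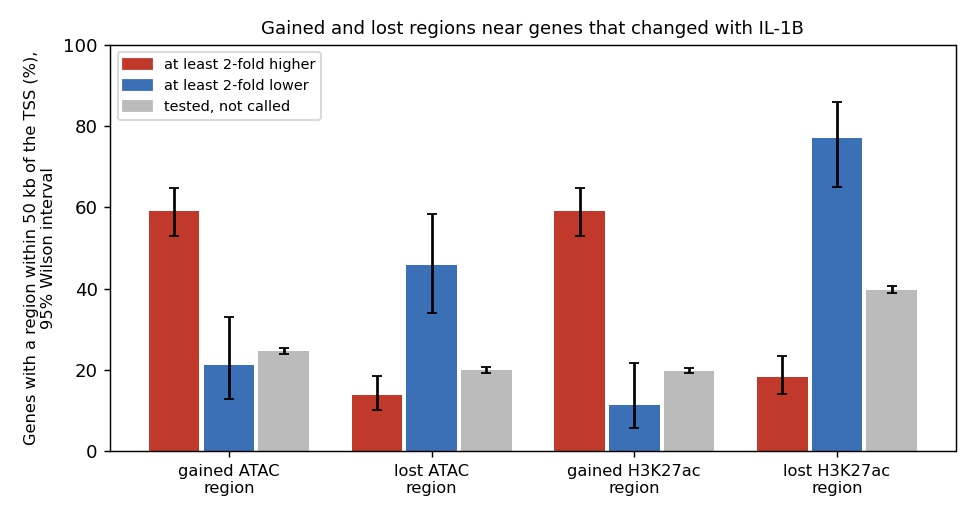
Share of genes with a gained or lost region within 50 kb of the transcription start, in percent with 95% Wilson intervals. Red bars are genes at least 2-fold higher with IL-1B (261) and blue bars genes at least 2-fold lower (61). Grey bars are tested genes not called at 2-fold, many of which changed by less. Gained regions lay near 59.0% of the genes that rose, and lost H3K27ac regions near 77.0% of those that fell.

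Common p65 sites were so widespread that most genes had one. Within 50 kb they were found for 96.9% of the genes that rose against 93.0% of genes not called at 2-fold (odds ratio 2.38, two-sided Fisher's exact test, adjusted p = 0.0161). They were found for 98.4% of the genes that fell (odds ratio 4.52, adjusted p = 0.14). For genes that rose the odds ratio was 1.54 within 10 kb (p = 0.0062) and 1.15 within 200 kb (p = 1). Within 10 kb the share was 68.9% for genes that fell (odds ratio 0.748, p = 0.302). Among named genes, p65 peaks of 36 of 36 donors covered the starts of SELE (chromosome 1, 169703206 to 169703397), VCAM1 (chromosome 1, 101185147 to 101185335) and CSF3 (chromosome 17, 38171469 to 38171657). TRAF1, GJA5, TMEM37, FAM110D, PDK4 and PPP1R3C had 0 common p65 sites within 10 kb of the start used. The window around TRAF1 also held 0 ATAC regions of any kind, and other starts of these genes were not examined. A common ERG site lay within 50 kb of 64.8% of the genes that rose against 73.8% of genes not called at 2-fold (odds ratio 0.653, two-sided Fisher's exact test, adjusted p = 0.00278). The odds ratio was 0.487 within 10 kb (p = 4.1e-08) and 0.713 within 200 kb, where the difference did not pass (p = 0.144). An ERG site lay near 83.6% of the genes that fell (odds ratio 1.81, adjusted p = 0.131). For these the odds ratio was 2.66 against genes matched on expression (p = 0.00397) and 0.919 within 10 kb (p = 0.798).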

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

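The counts of called genes and regions depended on the settings more than the direction of the main changes did. Of 1395 alternative values, 1330 were labelled the same as the main value. For a count this meant a change within 1.5-fold, and not a call or a direction. Of the 1395 values, 1089 belonged to named genes, and 1078 of these kept their call and direction. Many named genes were picked for large changes that went the same way in most donors. The share that held is thus partly built in by the choice of genes. Replicate 1 alone, replicate 2 alone, the donor F tests in untreated and IL-1B cells and the donor by treatment interaction were not run, because the deposited table pools the libraries of each donor. Where a value moved, the cause was not tested, except that pairs were also drawn at random to see what fewer pairs give.

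Among RNA counts, the 61 genes at least 2-fold lower became 329 with a pseudocount of 0.1, 29 with a mean of at least 5 RPKM and 37 after quantile normalization, and the 6597 lower at any size became 4204 at 5 RPKM or more. Without the donor block, unpaired limma called 3249 genes higher and 5608 lower. Camera called 13 lists higher with the preset correlation and 0 with an estimated correlation, where 7 of 26 had an unadjusted p under 0.05. With values corrected for the ceiling it called 1 list lower, the cell cycle list, and the cholesterol list turned to a median of -0.007. Two-sided limma differences turned for MYLK (0.014, adjusted p = 0.596) and ITGAX (0.032, adjusted p = 0.174) after quantile normalization.

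For ATAC peaks per library, the difference of -567.1 over 37 pairs turned to 3666 without the donor block, which also brought in the unpaired libraries (p = 0.657) and to 157.5 among the higher-scoring 50% of peaks (p = 0.978). For H3K27ac peaks per library, the difference among the higher-scoring 50% was -3960 (p = 0.0933). ATAC gains went from 6218 to 10412 without the block and with all libraries, to 2560 with the same number of top-scoring peaks and to 0 in 21 pairs matched on tags in peaks, where the McNemar test left 13553 regions with an unadjusted p under 0.05. ATAC losses went from 2497 to 1133 with top-scoring peaks, to 1256 in 33 pairs matched on depth and to 0 in the 21 pairs. Drawn at random, 21 pairs also gave medians of 0, up to 1462 gained and 322 lost, and 33 pairs a median of 1482 lost (1063 to 1875). H3K27ac gains went from 5213 to 3332 with top-scoring peaks and 2472 in 20 pairs matched on depth. H3K27ac losses went from 9266 to 4370, to 3184 in the same pairs and to 15127 when peaks had to cover 50% of the region. Drawn at random, 20 H3K27ac pairs gave medians of 2043.5 gained (1615 to 2445) and 3371.5 lost (2092 to 3946), so fewer pairs alone also lowered both counts. The 2472 gained in depth-matched pairs lay above the random range and the 3184 lost lay within it. Of the called regions 43.7% were gained in these pairs, against 36.0% in all pairs, so the lean toward losses was smaller with matched depth.

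Common p65 sites went from 50348 to 26827 for the upper part of each library by score and to 30450 in at least 3 in 4 donors, and ERG sites from 17163 to 9625 and 8523. The odds ratio of p65 sites in lost ATAC regions was 0.96 with sites in 1 in 4 donors and 1.01 with all uncalled regions as background, and that of ERG sites in lost H3K27ac regions turned to 0.623 with that background. Against regions of the same occupancy in the state where the factor was mapped, the odds ratios of p65 sites in lost regions turned to 1.69 (ATAC) and 1.34 (H3K27ac), and ERG sites were at 0.919 (p = 0.44) in gained ATAC, 1.19 (p = 0.171) in gained H3K27ac and 1.0 (p = 0.921) in lost H3K27ac regions. For p65 sites near genes it was 1.15 within 200 kb of higher genes, and for lower genes 6.55 against genes matched on expression (p = 0.0329) and 0.748 within 10 kb. For ERG sites near lower genes it was 2.66 against matched genes (p = 0.00397) and turned to 0.919 within 10 kb. For lost ATAC regions near higher genes it was 0.717 against matched genes (p = 0.0753).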

Other observations

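The tests of p65 peaks, of scaling and of positions counted once were chosen after the results were seen, as were most of the 11 correlations over donors. Few regions gained with IL-1B lay within 1 kb of a transcription start. Within 1 kb of a transcription start were 3.81% of gained ATAC regions (95% Wilson interval 3.36 to 4.32), against 18.6% of lost and 21.2% of uncalled ones. For H3K27ac the shares were 2.95% of gained, 6.43% of lost and 22.3% of uncalled regions. Common p65 sites lay there in 17.8% and common ERG sites in 26.9%. The uncalled regions were not matched on occupancy. A region called in nearly all untreated libraries cannot be called gained, whatever its signal. These shares therefore cannot tell a distance of gains from promoters from the way gains were called. Many p65 sites were in chromatin that was already open, since 57.8% of common p65 sites lay in ATAC regions found in at least 50% of untreated libraries.

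The total numbers of called genes and regions were compared with those of random swaps of the treatments within donors. The real assignment called 322 genes at 2-fold, 10547 genes at any size, 8715 ATAC regions and 14479 H3K27ac regions. The highest of the other swaps called 0 in each case, and 1 of 100 assignments, the real one, reached each count. Swapping large differences that went the same way lowers their mean and widens their spread, so low counts in the swaps were largely built in. The swaps speak only to the total counts, and do not exclude chance for any single gene or region.

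More genes fell than rose, and 3 technical explanations were weighed. The lean toward falls was strongest in weakly expressed genes. The median log2 difference was -0.169 in genes under 10% of the ceiling and -0.05 at 10 to 25%. It was 0.026 at 25 to 50% and 0.06 at 50 to 100%. If scaling to column totals were the cause, about equal numbers might rise with equal medians, and 47.87% did, but centring moves this value toward 50% whatever the cause, so that test cannot tell. For the counting of each position once, 34.62% of called genes rose in values corrected for the ceiling, against 37.45% without correction. The correction therefore did not even out the numbers. It took out only part of the relation with the ceiling, so this test cannot exclude the explanation. If deeper untreated columns were the cause, more genes should rise in the 16 donors with the deeper IL-1B column. In these 25.2% rose, against 44.6% in the other 37, which argues against that cause. The median log2 difference was -0.109 in the 16 donors and -0.024 in the 37. Direction thus differed by which column was deeper, and an effect of depth the other way was not excluded.

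In 7 of 53 donors the RNA response was outlying low, and libraries mixed up or mixed between treatments, or untreated cultures already partly activated, could each give this. The test was the correlation over 42 donors of the untreated RNA level of the induced genes with the share of gained H3K27ac regions called in the untreated library. It gave r = 0.149 (permutation p = 0.346, 95% interval -0.162 to 0.433, adjusted p = 0.423 over 11 relations), rho = 0.322 (p = 0.0381) and r = 0.324 without the 2 farthest donors. The value of r lay in the range predicted beforehand for mixed libraries, but its interval and rho reached the range predicted for activated cultures, so both explanations stayed undecided. The same relation for ATAC over 44 donors gave r = 0.566 (permutation p = 0.0004, adjusted p = 0.00147 over 11 relations), rho = 0.265 (p = 0.0817) and r = 0.59 without the 2 farthest.

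Abundant genes followed the ceiling across donors, which fits the counting of each position once. In genes at 50 to 100% of the ceiling the median r of untreated abundance with the ceiling was 0.867, against -0.137 in genes under 10% of it. After correction the values were 0.63 and -0.162, so the correction took out only part of this relation.

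Donors with more p65 peaks had larger RNA responses. Over 36 donors r was 0.572 (permutation p = 0.00019, adjusted p = 0.00105 over 11 relations), rho 0.547 (p = 0.00068) and r = 0.611 without the 2 farthest, and with the p65 depth taken out r was 0.507 (p = 0.00137) and rho 0.498. The number of p65 peaks went with a lower untreated level of the induced genes (r = -0.507) and not with their IL-1B level (r = 0.0543, p = 0.753), and in the 30 donors without outlying responses r was 0.358 (p = 0.0524). The value met the limits written for the hypothesis that more p65 peaks go with a stronger response, but since it did not hold without the outlying donors the hypothesis was left undecided.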
